A study of Mus musculus with 2 samples.

How the data were processed

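Small RNA was sequenced from hearts of mouse embryos of strain B6NCrl at embryonic day 16.5 (E16.5). The labels describe microRNA-seq with a size range under 30 (unit not given) from total RNA of healthy embryos of both sexes. The 2 libraries are labelled biological replicates of one group, each from its own pool of hearts. Replicate 2 came from 41 embryos per the labels, and the pool size of replicate 1 was not given by the labels used here.

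The deposited values are raw counts of reads per miRNA gene. Per the list of files deposited with each library, the counts were made on genome build mm10 with annotation M4. The aligner, the counter and any read trimming were not given in the sources used here. Each deposited table had 3 count columns, which held reads of either strand and of each strand separately. Its first 4 lines counted unmapped reads, reads matching several places, reads outside the listed genes and ambiguous reads. These lines name no gene and stayed out of all gene totals. The strand of each column was not stated in the sources used here. The strand column with the larger gene total in both libraries was taken as sense, by a rule set before the data were examined.

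Each library held 15207730 (replicate 1) and 12885555 (replicate 2) reads. Sense counts at miRNA genes came to 6473482 and 5841568, or 42.6% and 45.3% of reads. Reads matching several places were counted in no gene and made up 29.5% and 31.9% of reads. Unmapped reads made up 22.4% and 17.2%, reads outside the listed genes 2.99% and 2.66%, and no read was ambiguous. A count of 0 allows up to 3 counts, which is 0.463 CPM (counts per 1000000 sense counts) in replicate 1 and 0.514 CPM in replicate 2. No molecular identifiers are given in the sources used here and PCR copies are not independent molecules, so intervals and floors cover counting error only.

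Counts were divided by the sense total of each library and multiplied by 1000000 to give CPM, the relative abundance used throughout. A gene was called detected with 10 or more counts in each library. The tables listed 1973 genes by Ensembl identifier. Symbols, coordinates, hairpin sequences and host genes came from GENCODE M21 of the same build, matched on the identifier without its version. M21 held 1894 of the listed genes, 1815 of them with the same version, and every detected gene was matched. A gene was placed in a host when another gene of the same strand that is not a miRNA gene spanned it. It was called exonic where it overlapped an exon of any transcript of that host.

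The 17 gene lists, the pairs of genes and the tests of the report were chosen before the data were examined, except where the text says otherwise. The lists covered muscle, endothelial, smooth muscle and fibroblast, erythroid, leukocyte, neural, liver, epithelial and pluripotency miRNAs. They also covered the let-7, miR-17-92, miR-23, miR-27 and miR-24, and miR-30 families, the imprinted Dlk1-Dio3 and H19 and Igf2 regions, the X-linked Mir322 and Mir503 cluster and hypoxia. No gene stood on more than 1 list. Genes named in the text were the 20 with the highest mean CPM, all measured muscle genes, the 2 highest of every other list and both genes of each pair. The rule also took up to 5 genes in each direction with the largest difference between libraries among those past the test with a mean of at least 10 CPM. Genes outside this rule were named after their values were seen.

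With a single group there is no contrast of conditions, so edgeR's quasi-likelihood test had nothing to test. TMM scaling and the dispersion were computed with edgeR 4.0.16 and an intercept-only design in R 4.3.3. The 2 libraries were compared gene by gene with a two-sided exact binomial test on the counts, given the TMM-scaled library sizes. P-values were adjusted by the Benjamini-Hochberg method over the 365 detected genes. A call needed an adjusted p under 0.05 and at least a 2-fold difference. This test compares the 2 libraries, not conditions. The log2 ratios of replicate 2 over replicate 1 were computed from TMM-scaled counts with 0.5 added to each count. Shares of counts carry Wilson 95% intervals, and ratios of 2 genes exact Clopper-Pearson intervals. Levels and ratios of different genes compare read counts, and whether different miRNAs were read with equal efficiency was not tested.

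The level and the difference of each list with at least 3 detected genes were placed among 10000 random lists of the same size. For differences the random genes were matched on mean expression in 10 bins, and percentiles under 2.5 or over 97.5 were taken as apart. Correlations across genes used log2(CPM + 1). Genes were checked for reads they could share by finding 20-base sequences common to 2 or more miRNA hairpins. Alternatives were total-count scaling, DESeq2 1.42.0 size factors, no count filter, no minimum fold, other detection limits, the unstranded column, shares without the most abundant gene and leaving out each replicate. Python 3.11.15, scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3 were used.

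The comparison of the 2 libraries was tested on simulated data with counts drawn from the real means and library sizes and 200 genes changed. With counting error only, 98.8% of the genes changed by 1.5 on the log2 scale and 99.0% of those changed by 2.0 were called, and 0 of the 180 unchanged genes (361 genes tested). With the estimated spread between pools added, the shares were 83.0% and 100%, and 0.585% of 171 unchanged genes were called (360 genes tested). All simulated calls needed the 2-fold minimum. Changes near the 2-fold limit were not simulated, so these shares do not apply to them.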

Results

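The miRNA content of the E16.5 mouse heart was measured by microRNA-seq in 2 libraries from separate pools of hearts. The libraries held 6473482 and 5841568 sense counts at miRNA genes. The labels define a single group, so the questions addressed were which miRNAs made up the heart libraries and how far the 2 pools differed. Of 1973 listed miRNA genes, 365 were detected in both libraries and 1248 had no count in either. Values are given as mean ± SD over the 2 libraries (n = 2) unless stated otherwise. Coordinates are those of mm10.

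By sense counts at the listed genes, the most abundant miRNA gene was Mir143, a smooth muscle miRNA, at 96423 ± 348 CPM. Mir126a, an endothelial miRNA, followed at 85049 ± 1170 CPM, then Mir335 at 82574 ± 15687 CPM and Mir322 at 72099 ± 6195 CPM. Mir99a (58613 ± 318 CPM) and the heart muscle miRNA Mir208b (58261 ± 1172 CPM) were next, with the let-7 genes Mirlet7i (56944 ± 2111 CPM) and Mirlet7g (52420 ± 3280 CPM). Mir26b reached 32861 ± 2274 CPM and Mir30e 28556 ± 2035 CPM. The remaining members of the 20 highest were Mir351, Mir23a, Mir23b, Mir130a, Mir99b, Mirlet7d, Mir21a, Mir30a, Mir17 and Mir30d, from 25049 CPM for Mir351 down to 12332 CPM for Mir30d. Mir143 alone held 9.64% ± 0.03 of sense counts, the 10 highest genes 62.4% ± 1.1, the 20 highest 78.5% ± 0.07 and the 50 highest 91.0% ± 0.10. Mir378a, not among the listed genes, would stand at rank 9 with 44998 ± 2198 CPM if the opposite-strand counts at Gm25301 were assigned to it, a step chosen after seeing the data. In all, 82 listed genes had a mean of at least 1000 CPM and 22 of at least 10000 CPM. Reads matching several places, 29.5% of reads in replicate 1 and 31.9% in replicate 2, were counted in no gene. These ranks and shares therefore leave out any reads common to several miRNA genes, and the order with all reads is not known.

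**Figure D1:**
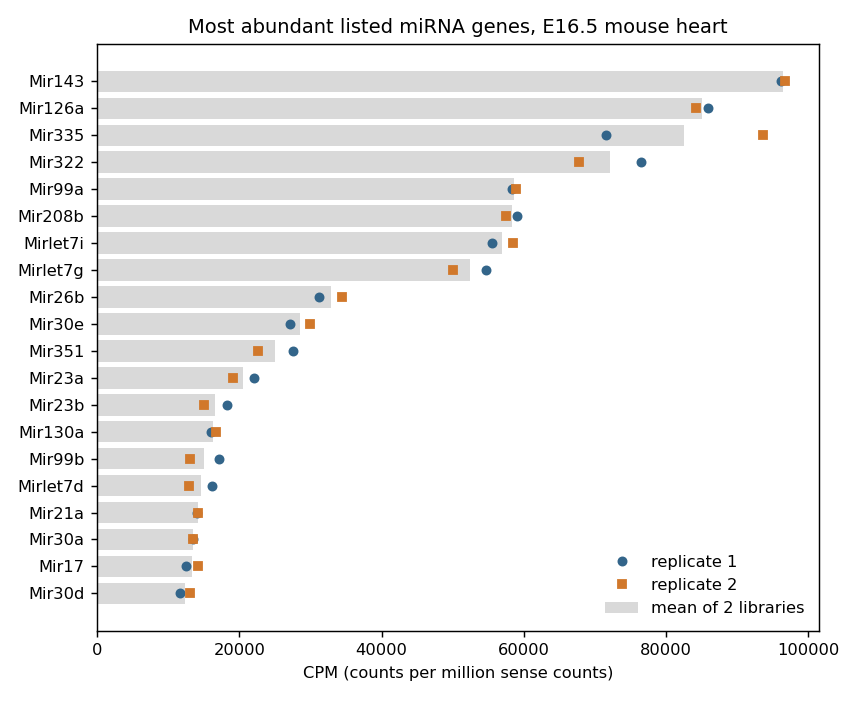
Levels of the 20 listed miRNA genes with the most sense counts in E16.5 mouse heart, in CPM of sense counts. Genes not listed, such as Mir378a, are not drawn, and reads matching several places are not counted. Grey bars are means of the 2 libraries and symbols are the single libraries; Mir143 is highest at 96177 and 96669 CPM, and Mir335 shows the largest gap among the 20, at 71482 and 93667 CPM.

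These genes lay in different settings in the genome. Mir143 (ENSMUSG00000065445.2; chromosome 18, 61649196 to 61649258, minus strand) lay in no annotated host gene of its strand. Mir126a (ENSMUSG00000065540.1; chromosome 2, 26591357 to 26591429, plus strand) overlapped an exon of an annotated transcript of Egfl7, an endothelial gene. Mir335 (ENSMUSG00000065501.1; chromosome 6, 30741299 to 30741396, plus strand) was intronic in the imprinted gene Mest. Mir322 (ENSMUSG00000065418.1; chromosome X, 53054255 to 53054349, minus strand) had no annotated host. Mir99a was intronic in Mir99ahg, Mirlet7g in Wdr82, Mir26b in Ctdsp1 and Mir30e in Nfyc.

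The muscle miRNAs were led by the genes within cardiac myosin genes. Mir208b, intronic in the beta myosin heavy chain gene Myh7 (chromosome 14, 54975700 to 54975776, minus strand), stood at 58261 ± 1172 CPM. Mir208a, intronic in the alpha myosin heavy chain gene Myh6 (chromosome 14, 54949060 to 54949142, minus strand), stood at 6556 ± 746 CPM. Mir499, intronic in Myh7b (chromosome 2, 155622880 to 155622958, plus strand), stood at 2594 ± 13.6 CPM. Mir208b exceeded Mir208a 9.80-fold in replicate 1 and 8.11-fold in replicate 2, a log2 ratio of 3.16 ± 0.19. The exact 95% intervals on the log2 scale were 3.28 to 3.31 and 3.004 to 3.03, so the 2 libraries differed by more than counting error while both placed Mir208b far above Mir208a. The log2 ratio of Mir499 over Mir208a was -1.33 ± 0.16.

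Other muscle miRNAs had few counts. Mir206, a skeletal muscle miRNA, had 742 counts in replicate 1 and 1369 in replicate 2 (174 ± 84.7 CPM). Mir133b had 26 and 27 counts, Mir1a-1 19 and 11, Mir133a-1 19 and 14, Mir1b 6 and 13, and Mir133a-2 0 and 3. A count of 0 for Mir133a-2 in replicate 1 allows up to 0.463 CPM. The hairpin of Mir1a-1 shared a 20-base sequence with 1 other hairpin, and those of Mir133a-1, Mir133a-2 and Mir133b each with 2. Reads matching several places were counted in no gene, so the levels of these genes are uncertain. Mir1a-2 was not among the listed genes, but it lies on the other strand at Mir1b, where 115 and 135 opposite-strand counts were found. Because Mir1a-2 had no sense count of its own and Mir133a-2 was below 10 counts, the ratios of Mir1a-2 over Mir1a-1 and of Mir133a-1 over Mir133a-2 were not analysed here. Together the muscle list held 6.76% ± 0.03 of sense counts, with 7 of 9 measured genes detected.

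Among counted reads, smooth muscle and fibroblast miRNAs and endothelial miRNAs each held a larger share than the muscle list, by more than the spread between libraries. Reads shared by miR-1a or miR-133a copies are missing from the muscle list. The smooth muscle and fibroblast list also lacks shared reads, as Mir199a-2 and Mir199b each shared a 20-base sequence with 2 other hairpins. The order of these lists with all reads is therefore not known. The smooth muscle and fibroblast list held 11.5% ± 0.04 of sense counts (9 of 12 detected), mostly through Mir143, with Mir21a at 14148 ± 117 CPM and Mir145a at 1288 ± 182 CPM. Without Mir143 in the list and in the total, its share was 2.04%. Mir143 and Mir145a are neighbours on chromosome 18, and Mir143 was 82.9-fold and 68.2-fold higher than Mir145a in the 2 libraries, a log2 ratio of 6.23 ± 0.20. The endothelial list held 8.52% ± 0.11 (3 of 3 detected), nearly all of it Mir126a, while Mir221 stood at 84.2 ± 21.2 CPM.

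The lists of blood miRNAs and of miRNAs of other organs held low shares. The erythroid list held 0.196% ± 0.022 (3 of 3 detected), with Mir451a at 1511 ± 209 CPM and Mir144 at 368 ± 16.3 CPM. The log2 ratio of Mir451a over its neighbour Mir144 was 2.03 ± 0.14, and that of the endothelial Mir126a over Mir451a 5.82 ± 0.18. The leukocyte list held 0.0746% ± 0.011 (4 of 6 detected), led among the listed genes by the myeloid Mir223 at 402 ± 3.79 CPM and by Mir155 at 222 ± 82.2 CPM. Counting reads of either strand raised the leukocyte share to 0.310%, through the 11332 and 19615 opposite-strand counts at Mir142b, where Mir142 lies on the other strand; assigned to Mir142 they gave 2402 ± 1062 CPM, above Mir223. The neural list held 0.0801% ± 0.011 (10 of 16 detected), with Mir128-1 at 240.4 ± 74.5 CPM and Mir132 at 199.6 ± 23.2 CPM. The listed miR-124 copies had 0 or 1 count per library, Mir9-2 had 0 in both, and Mir9-3 had 16 in replicate 1 and 1 in replicate 2. Mir128-1 shared a 20-base sequence with 1 other hairpin, as did the miR-124 and miR-9 copies with 2 each, so any reads matching several of them are not in the neural share. Mir122, a hepatocyte miRNA and the only liver gene tested, stood at 161 ± 0.97 CPM, or 0.0161% of counts.

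Epithelial miRNAs were all detected (12 of 12) and held 0.657% ± 0.089 of counts. Mir429 stood at 1819 ± 443 CPM and Mir200c at 1188 ± 298 CPM. The pluripotency list held 0.0596% ± 0.0056 (7 of 12 detected), with Mir302a at 238 ± 31.6 CPM and Mir302d at 185 ± 13.9 CPM. Mir210, a hypoxia-induced miRNA, stood at 742 ± 51.6 CPM, or 0.0742% ± 0.0052 of counts.

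Of the families and clusters, let-7 held the largest share at 13.6% ± 0.33 (10 of 10 detected). Of its genes, 5 shared a 20-base sequence with other hairpins and Mirlet7e and Mirlet7f-1 were not among the listed genes, so the share does not hold all reads of the family. The X-linked Mir322 and Mir503 cluster held 10.2% ± 0.99 (7 of 7), with Mir351 at 25049 ± 3432 CPM and Mir503 at 1828 ± 289 CPM. Mir322 exceeded Mir503 with a log2 ratio of 5.31 ± 0.10. The miR-30 family held 5.48% ± 0.32 (6 of 6) and the miR-23, miR-27 and miR-24 genes 3.92% ± 0.45 (5 of 5). Mir23a (20535 ± 2122 CPM) and Mir23b (16606 ± 2335 CPM) shared a 20-base sequence, and any reads matching both were counted in neither. Mir27a, Mir27b and Mir24-2 each shared one with 1 other hairpin, and Mir24-1 was not among the listed genes. The miR-17-92 cluster and its paralogues held 3.20% ± 0.37 (15 of 15), with Mir17 at 13389 ± 1189 CPM and Mir93, in the host gene Mcm7, at 5351 ± 919 CPM. Mir30c-1, Mir30c-2, Mir450-1, Mir450-2, Mir92-1 and Mir92-2 also each shared a 20-base sequence with 1 other hairpin. As for let-7, the shares of these families and clusters therefore need not hold all their reads.

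Imprinted regions were also represented. The Dlk1-Dio3 region on chromosome 12 held 3.06% ± 0.09 of counts, with 41 of 46 measured genes detected. Its highest genes were Mir411 at 5610 ± 252 CPM and Mir487b at 4710 ± 261 CPM, each sharing a 20-base sequence with 1 other hairpin. In the H19 and Igf2 region both genes were detected and held 0.246% ± 0.019. Mir483 stood at 2358 ± 175 CPM, and Mir675, within H19, at 102 ± 14.6 CPM.

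Against random lists of detected genes in the same library, the median level of the let-7 family lay at the 99.97th percentile in both libraries. The Mir322 and Mir503 cluster lay at percentiles 98.7 and 98.0, the miR-30 family at 97.8 and 99.1, the epithelial list at 95.7 and 95.03 and the miR-23, miR-27 and miR-24 genes at 94.5 and 94.4. The smooth muscle and fibroblast list lay at 88.8 and 90.03, Dlk1-Dio3 at 79.5 and 79.7, miR-17-92 at 75.0 and 93.6 and the erythroid list at 75.5 and 74.9. The remaining lists were the muscle list at 50.3 and 74.4, the leukocyte list at 53.4 and 62.8 and the endothelial list at 39.6 and 47.7. The neural list lay at 27.5 and 31.8 and the pluripotency list at 16.2 and 14.0. The median gene of the muscle list was Mir206, at 115 CPM in replicate 1 and 234 CPM in replicate 2, so the muscle percentiles follow that gene. Below it stood Mir1a-1, Mir133a-1 and Mir133b, for which reads matching several places are not counted. The muscle percentiles therefore do not place the heart muscle miRNAs as a set. Genes are not independent replicates, so these percentiles describe the 2 libraries and carry no p-value.

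The 2 pools were then compared with each other. Mir20b was 3.02-fold, Mir106a 2.66-fold and Mir363 2.01-fold higher in replicate 2, and all 3 lie within a short stretch of the X chromosome (52741693 to 52741767 for Mir363, 52742503 to 52742567 for Mir106a). Mir206 (2.08-fold) and Mir147 (2.09-fold) were also higher in replicate 2. Mir135b was 4.51-fold, Mir92b 2.99-fold and Mir153 2.12-fold lower in replicate 2. By the exact binomial test with Benjamini-Hochberg adjustment, the adjusted p was 1.21e-174 for Mir20b, 1.83e-179 for Mir106a, 5.62e-68 for Mir363, 5.3e-60 for Mir206, 7.16e-118 for Mir92b, 2.59e-59 for Mir135b, 0.000162 for Mir147 and 0.000124 for Mir153. In all, 12 of 365 genes passed, 6 higher and 6 lower in replicate 2. The 4 others had a mean under 10 CPM: Mir1969 was higher and Mir196a-2, Mir7018 and Mir211 were lower in replicate 2. Mir363 lay at the 2-fold limit and was not called with total-count scaling or DESeq2 size factors. The p-values rest on counting error alone and compare these 2 libraries.

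**Figure D2:**
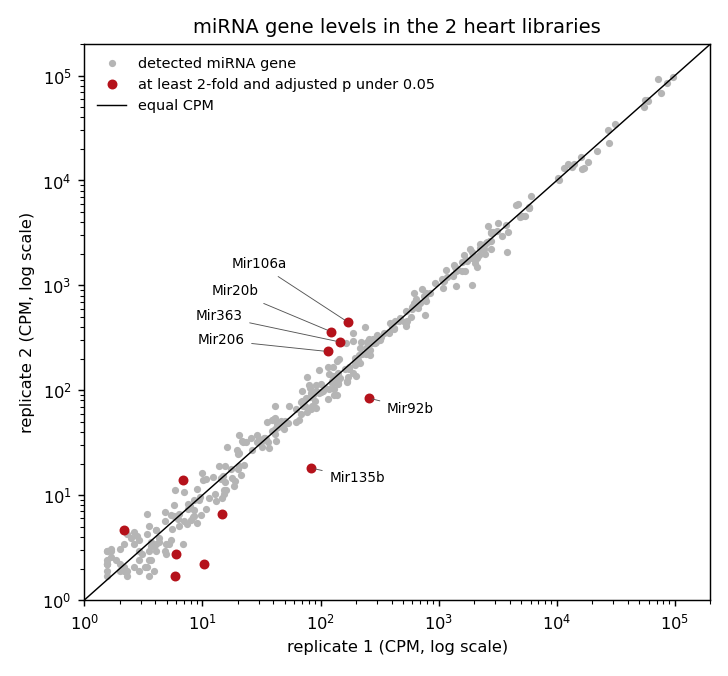
Level of each of the 365 detected miRNA genes in replicate 1 (x axis) against replicate 2 (y axis), in CPM on log axes. Red points are the 12 genes past the exact binomial test with at least a 2-fold difference, and the line marks equal CPM; the most abundant of the 12, Mir106a, has a mean of 309 CPM.

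Across all detected genes most levels lay close together in the 2 pools. Pearson's r of log2(CPM + 1) across the 365 genes was 0.994 and Spearman's rho 0.991, where genes are not independent replicates. The median absolute log2 ratio was 0.21 for detected genes, against 0.048 from counting error alone, and 0.14 for the 187 genes with at least 100 CPM. Of the detected genes, 86.6% lay within 1.5-fold and 96.7% within 2-fold. The largest absolute log2 ratio among the 20 most abundant genes was 0.42, for Mir335 (1.33-fold higher in replicate 2). The biological coefficient of variation from edgeR was 17.6%. The chi-square of the counts was 166 per gene, which goes against repeat deposits of one library and says nothing on whether the pools were separate; the labels give them as biological replicates.

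The list with the clearest difference was miR-17-92 and its paralogues, which was higher in replicate 2 with a median log2 ratio of 0.38 (percentile 100 of random lists). Of its 15 genes, 12 were higher in replicate 2, 0 were lower and 3 did not pass, adjusted over all genes or over the list alone. The counts in this paragraph have no minimum fold. Without that minimum, 169 of all 365 detected genes passed, 95 higher and 74 lower in replicate 2. With the 2-fold minimum, 3 genes of the miR-17-92 list passed, and 0 of the epithelial and Dlk1-Dio3 lists. Mir93 was 1.30-fold and Mir17 1.15-fold higher. The epithelial list had a median log2 ratio of -0.19 (percentile 0.695), with 1 gene higher, 6 lower and 5 not past the test, the same adjusted over the list alone. Mir429 was 1.39-fold and Mir200c 1.41-fold lower in replicate 2, while Mir205, named after its value was seen, was 1.39-fold higher. The Dlk1-Dio3 list had a small shift of -0.059 (percentile 1.39), with 5 genes higher, 12 lower and 24 not past the test, again the same adjusted over the list alone. Random lists were matched on expression and not on position, and no allowance was made for the number of lists. The miR-17-92 genes and paralogues lie in clusters on chromosomes 14, X and 5, and the Dlk1-Dio3 genes in 1 region. The miR-200 genes of the epithelial list lie on chromosomes 4 and 6. If neighbouring genes shift together, these percentiles are more extreme than those of unlinked genes.

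The other 11 lists lay within the central range of random lists. Genes past the test are again counted without a minimum fold. With the 2-fold minimum, 1 gene of the muscle list passed, Mir206, and 0 genes of the other lists in this paragraph. The leukocyte list had a median log2 ratio of 0.45 (percentile 94.2), with Mir155 1.74-fold higher in replicate 2 and 3 of 4 genes past the test, the same adjusted over the list alone. With opposite-strand counts given to Mir142, an alternative chosen after seeing the data, its percentile was 98.67. The neural list stood at 0.23 (percentile 94.2), with Mir128-1 1.59-fold higher, and had 4 genes higher, 1 lower and 5 not past the test. The miR-30 family stood at 0.18 (percentile 91.2), with 5 of 6 genes higher and 0 lower. The smooth muscle and fibroblast list stood at 0.053 (percentile 56.7), with 5 of 9 genes higher and 1 lower. The endothelial list stood at 0.078 (percentile 57.5), where Mir221 was 1.46-fold higher, and the muscle list at 0.036 (percentile 64.8). In the muscle list 2 genes were higher and 1 lower, and 3 higher and 1 lower when adjusted over the list alone, which added Mir499 at 1.03-fold. The Mir322 and Mir503 cluster stood at -0.15 (percentile 5.26), with 4 of 7 genes lower and 1 higher. The erythroid list stood at -0.065 (percentile 18.6), where Mir451a was 1.20-fold lower in replicate 2. The miR-23, miR-27 and miR-24 genes stood at -0.0054 (percentile 30.5), with 2 of 5 lower and 1 higher. With opposite-strand counts given to Mir24-1, an alternative chosen after seeing the data, they stood at -0.099 (percentile 4.2). The let-7 family stood at -0.029 (percentile 35.6), with 3 of 10 higher and 5 lower. The pluripotency list stood at -0.17 (percentile 14.0), where 2 of 7 genes were lower, and 1 when adjusted over the list alone. For the lists in this paragraph not given a separate count, the numbers past the test adjusted over the list alone equalled those adjusted over all genes.

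**Figure D3:**
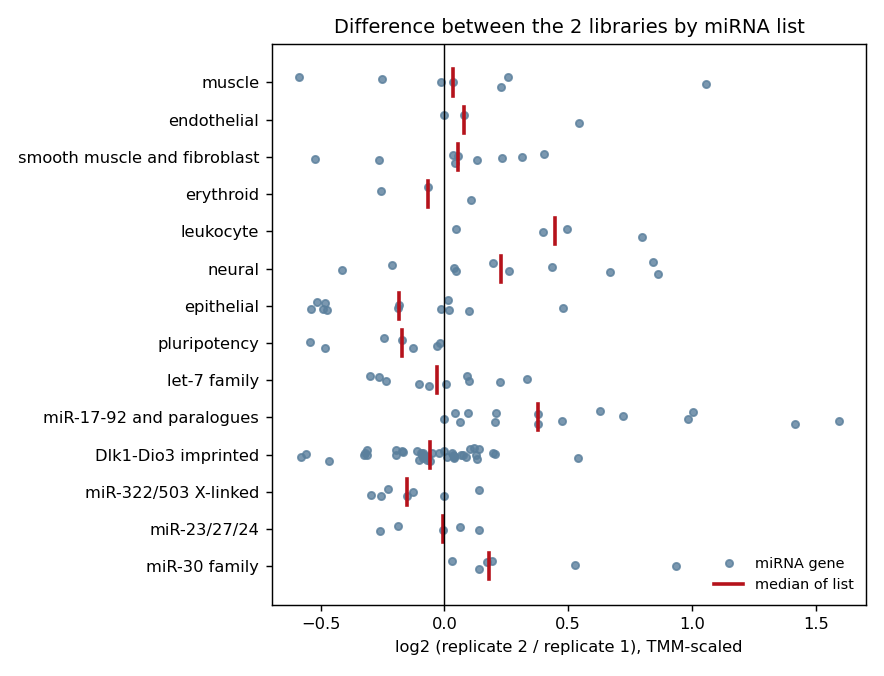
The log2 ratio of replicate 2 over replicate 1 (x axis, TMM-scaled) of each detected gene in the 14 lists with at least 3 detected genes. Points are genes and red bars list medians; miR-17-92 and its paralogues have the median 0.38 with 14 of 15 genes above 0, and the epithelial list the median -0.19 with 8 of 12 genes below 0, or 10 of 12 with total-count scaling or DESeq2 size factors.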

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

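The tests of counts on the opposite strand and of the miR-1a and miR-133a copies were chosen only after the results were seen.

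Counts on the strand opposite to the listed genes, which the comparisons do not use, made up 5.70% of gene-assigned counts of either strand in replicate 1 and 6.10% in replicate 2, far above the limit of 3 counts that a count of 0 allows. They lay at a few genes. Gm25301 had 298224 and 289603 opposite-strand counts in replicates 1 and 2, Gm25927 had 28520 and 26199, Gm24321 had 18572 and 12818, Gm24083 had 15563 and 15853, and Mir142b had 11332 and 19615. A loss of strand information in the libraries was argued against: among genes with 10000 or more sense counts, the highest opposite-strand share was 0.0920%. Of opposite-strand counts, 99.96% in the lower library lay at listed genes overlapped by a miRNA gene of the other strand that was not among the listed genes. A candidate explanation is that these reads came from those genes, with Mir378a at Gm25301 (chromosome 18, 61397835 to 61397900, minus strand), Mirlet7e at Gm25927, Mir409 at Gm24321, Mir191 at Gm24083 and Mir142 at Mir142b. No biological explanation was tested.

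Given to the genes of that strand and added to the totals, the counts put Mir378a at 44998 ± 2198 CPM (SD, n = 2), which is rank 9. Mirlet7e stood at 4183 ± 40.1 CPM, Mir191 at 2408 ± 199 CPM, Mir409 at 2383 ± 456 CPM and Mir142 at 2402 ± 1062 CPM, the last 1.95-fold higher in replicate 2.

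Reads matching several places made up 29.5% of reads in replicate 1 and 31.9% in replicate 2, also above the limit of 3 counts, and were counted in no gene. The listed copies of miR-1a and miR-133a, known as heart muscle miRNAs, had 0 to 19 counts per library, and Mir1a-2, read from the 115 and 135 opposite-strand counts at Mir1b, stood at 19.2 ± 3.50 CPM (SD, n = 2). Reads matching several copies were counted in no gene, whatever their number, so these counts do not measure the abundance of miR-1a or miR-133a. A candidate explanation of the low counts is that most reads of these copies were set aside in this way. In 12 of 16 families that hold both kinds, the highest gene without a shared 20-base sequence exceeded the highest gene with one (exact binomial p = 0.0768), which did not pass 0.05. That test compares levels of different genes and cannot count the reads set aside, so the size of this loss stays open. The other explanation, low abundance of these miRNAs in the hearts, cannot be told apart from it, because the multimapping reads (at least 29.5% of reads) are numerous enough to hold them and carry no gene names. No biological difference was tested, as the labels give 1 group.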

How the results depend on the processing

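The tests that gave opposite-strand counts to the miRNA gene of that strand were chosen only after the results were seen. Of 165 alternative values, 131 stayed within the spread or on the same side of the limit, 30 moved, 3 passed a limit they had not passed or called more genes, and 1 reversed. Among the 131, 50 left out a replicate. With 2 libraries each single share or ratio lies within 1 SD of the mean by construction, so these say nothing about stability, and the comparison of the libraries needs both. Total-count scaling and DESeq2 size factors shift all genes alike, so list percentiles stayed, and 11 of the 12 genes were still called (not Mir363). Detection at 1 count in each library gave 594 genes. Without a count filter 21 genes differed between libraries, 11 of them among the 12 (not Mir1969), and without a minimum fold 169. The 10 highest genes held 60.5% of counts of either strand and 60.5% with opposite-strand counts reassigned. With counts of either strand, list shares were muscle 6.36%, endothelial 8.01%, smooth muscle and fibroblast 10.8%, leukocyte 0.310%, liver 0.0152%, let-7 12.8%, Dlk1-Dio3 2.88% and miR-30 5.15%. With reassigned counts they were 6.36%, 8.01%, 10.8%, 0.310%, 0.0151%, 13.2%, 3.32% and 5.15% in the same order. Without Mir143 they were muscle 7.48%, endothelial 9.43%, smooth muscle and fibroblast 2.04%, liver 0.0178%, pluripotency 0.0659%, let-7 15.1%, Dlk1-Dio3 3.39%, H19 and Igf2 0.272%, Mir322 and Mir503 cluster 11.3%, miR-30 6.06% and hypoxia 0.0821%. These shares moved because the total and the members changed. The leukocyte shift became 0.49 (percentile 98.67) with Mir142 added by reassignment. The shift of the miR-23, miR-27 and miR-24 genes became -0.099 (percentile 4.2) with Mir24-1 added, and that of the muscle list 0.13 (percentile 79.4) with Mir1a-2 added. No list other than the leukocyte list crossed a percentile limit by reassignment. Genes with numbered copies differed from other genes by -1.42 in median log2 CPM, and by 0.11 without a count filter, where 71 of 111 numbered and 1537 of 1862 other genes had under 10 counts in a library. A count of 0 allows up to 0.463 CPM in replicate 1 and 0.514 CPM in replicate 2. Detection needed 10 counts in each library, which is a higher limit.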

Other observations

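The miR-200 family was singled out after its values were seen, so all tests of it were chosen after that result, and the test of other epithelial genes also after its own.

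The X-linked Mir106a cluster, singled out after its values were seen and not tested as a list, held Mir92-2 (1.65-fold) and Mir18b (1.39-fold higher in replicate 2) beside Mir20b, Mir106a and Mir363, while Mir19b-2 at 13 and 18 counts did not pass the test. In the Mir322 and Mir503 cluster, 4 of 7 genes were lower and 1 higher in replicate 2 without a minimum fold. The list as a whole lay within the central range of random lists (percentile 5.26). Mir351 stood at 0.838-fold, Mir503 at 0.813-fold and Mir322 at 0.901-fold of replicate 1. Among other genes, Mir30b was 1.91-fold higher and Mir449a 0.540-fold of replicate 1. Mir92-2, Mir18b, Mir19b-2, Mir30b and Mir449a were named after their values were seen.

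The 5 genes of the miR-200 family (Mir200a, Mir200b, Mir200c, Mir141 and Mir429), on chromosomes 4 and 6, were lower in replicate 2 by nearly the same amount, with log2 ratios from -0.54 to -0.48 and a median of -0.49 (SD 0.025). A linear effect of hairpin GC content was argued against: after a linear correction for GC the median was -0.49. The hairpins had a GC content from 49.4% (Mir429) to 55.1% (Mir200c), and the GC content of the reads themselves was not tested. The 7 other epithelial genes did not share the shift of the miR-200 genes, with a median of 0.014 (SD 0.22, from -0.19 for Mir203 to 0.48 for Mir205). These values go against an equal carry-over of all epithelial-list genes in replicate 1. They cannot exclude a carry-over of some epithelium, because the test was chosen after the values were seen and 7 genes need not mark every kind. A carry-over of multiciliated airway epithelium in replicate 1 may account for the lower miR-200 counts and stays open, as does an untested difference between the embryos of the pools. Of the 4 genes named beforehand, Mir449b had 15 and 2 counts and no ratio was computed. Mir34b, Mir34c and Mir449c had a median of -0.059 (SD 0.51, from -0.61 to 0.40). This median met the bound set beforehand against the carry-over, a median above -0.1, and that bound named no spread. The margin was smaller than the spread of these genes, so the carry-over was not taken as excluded. Mir449a, not among the 4 and named after its value was seen, was lower in replicate 2 (12377 and 5921 counts, log2 ratio -0.89).

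Neighbouring genes were compared on the hypothesis that genes on one primary transcript have similar levels. The 110 adjacent pairs within 10 kb on one strand differed by a median of 3.25 on the log2 scale, against 3.66 for permuted levels (permutation test, two-sided, p = 0.30), and the 120 pairs within 50 kb by 3.10 (permutation p = 0.14). The prediction set beforehand for unrelated levels was a p of 0.05 or more, which is no bound on the difference, so it does not show that neighbours differ as much as random pairs.

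Of 111 genes with numbered copies, 71 were not detected, against 1537 of 1862 other genes. The 40 detected had a median of 48.2 CPM, at percentile 8.95 of random lists, but without the count filter the 111 genes lay at percentile 99.875, so no direction can be given.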
